A study of Mus musculus with 22 samples.

How the data were processed

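The values analysed were the log2 expression values as deposited. Per the submitters' processing notes they were made with the robust multi-array average (RMA) in the affy package 1.48.0 under R 3.4.3, from total RNA labelled with biotin. No value was transformed again. The image analysis settings are not given in the sources used here. All 22 sample columns of the table were used, and group, animal, replicate number and batch were taken from the sample labels.

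The table held 25428 probe sets. Of these, 24705 carried 1 gene symbol, 0 carried several and 723 carried none and stayed unnamed. Of the symbols, 1 was found on more than 1 probe set, and the probe set with the highest mean was kept. Probe sets were matched by Entrez number to reference genes (assembly GRCm38.p6) for chromosome and gene order, with 24673 matched. The assembly used by the authors is not given in the sources used here. A gene was tested if it lay above the table median of 4.57 in at least 3 arrays, which left 13871 genes.

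Genotype and sex were compared by limma (lmFit and eBayes) on 20 arrays, 1 per animal, with a mean for each of the 6 groups. The Batch1 array was used for the 2 animals hybridised in both batches. Diet was compared on all 22 arrays with a batch term and the animal as a random block (consensus correlation 0.228), since diet and batch overlapped except for these 2 animals. All p values are two-sided and from limma unless named otherwise, and were adjusted by Benjamini and Hochberg over all tested genes of a comparison. A gene was called at adjusted p below 0.05. The average over strata gave the 3 genotype differences equal weight. Exact permutation tests rearranged genotypes within strata. The sets of calls are those of limma unless another tool is named.

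Genes named for a comparison were the called genes with the largest differences, at most 10 in each direction, with the targeted genes first. Where fewer than 5 were called, the 5 with the smallest p were taken as well, and predicted genes could be left unnamed. Members named for a list were up to 4 with the smallest p in that comparison. The genes of iron handling were chosen after their values had been seen.

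Fixed gene lists were written before the data were examined. They cover metabolic pathways, stress and immune responses, cell type markers, sex-biased liver genes and the neighbours of the targeted genes. In each comparison, 28 lists were tested against all other genes by camera from limma with its preset correlation between genes of 0.01, and adjusted over the 28. Camera was repeated with the correlation estimated from the data, and fry was run as a self-contained test. For the diet fit the values and the design were first whitened for the animal block. Members were also adjusted over the list alone. Over the 10 comparisons, 62 list calls were made at the preset correlation.

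Alternatives were no expression filter, a stricter filter (10 arrays), all probe sets kept, quantile normalisation again, a variance trend with robust moderation, a fold threshold of 1.5, a replicate block, only the groups compared, all 22 arrays with batch term and animal block, technical repeats averaged, no batch term, Batch2 arrays alone, and each animal left out in turn. Leaving out together female WT 2 and male KO 3 on HFHS, whose first arrays deviated most from their group (SD over genes 0.268 and 0.272, with male KO 1 on HFHS close at 0.259 and male WT 2 on chow at 0.233), was added once the values had been seen. Every comparison was also run on the other ways of splitting its animals, up to 100.

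A self-test planted known changes in simulated arrays of the same design with 13871 independent genes. At a log2 change of 1, 50% of the planted genes were recovered in the genotype by sex interaction and 62% to 98% in the other comparisons. At a change of 0.5 the share was 76% for the averaged genotype difference and between 2% and 38% for the others. No planted gene was called in the wrong direction. With no change planted, 0 to 2 genes and 0 to 1 lists were called in 10 simulations of each comparison. The simulated genes were independent and every simulated Batch2 array carried the same batch shift. These rates therefore do not carry over to lists of correlated genes or to the diet comparisons in the real arrays.

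The work was done in R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.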

Results

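Liver RNA from 20 C57BL/6 mice was profiled on 22 single-colour expression arrays. The mice were wild type (WT) or lacked the arylamine N-acetyltransferase genes Nat1 and Nat2 (KO), and the WT animals were littermate controls per the labels. The series title names the purpose, namely how loss of these enzymes affects energy metabolism and the oxidation of fatty acids. Males received either a high-fat, high-sucrose diet (HFHS) or regular chow, and females received the HFHS diet only. Fat supplied 45% of the energy of the HFHS diet and 13.5% of that of chow, and carbohydrate 35% and 61.3%. There were 3 female WT, 3 female KO, 3 male WT and 3 male KO animals on HFHS, and 4 male WT and 4 male KO animals on chow. The design text counts 4 males in each HFHS group, but the sample titles show 3 animals and 1 technical repeat, so n = 3 was used. Diets lasted 12 weeks from an age of 12 weeks. The protocol can also be read as chow first and HFHS afterwards, in which case diet and age would differ together. The 12 arrays of Batch1 held all females and 1 array of every HFHS male, and the 10 arrays of Batch2 held all chow males and a second array of WT HFHS male 1 and KO HFHS male 3. Array medians lay between 4.47 and 4.62 on the log2 scale. The first principal component held 30.7% of the variance, with negative scores in all 6 females and positive scores in all 8 chow males. On the third component (7.48%) 3 animals lay apart from their groups, namely male KO 3 on HFHS (−30.0 against −0.28 and −0.05), female WT 2 (−15.0 against 8.12 and 8.16) and male WT 2 on chow (−12.4 against 3.97 to 10.3).

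The targeted genes were read first, in every animal. Nat2, which encodes the enzyme that acetylates arylamine drugs and carcinogens, was 6.89 ± 0.23 in WT (SD, n = 10, range 6.42 to 7.31) and 3.88 ± 0.17 in KO (SD, n = 10, range 3.50 to 4.11). It was therefore 8.16-fold lower in KO averaged over the 3 strata (log2 difference −3.03 ± 0.09 SE, limma adjusted p = 2.77e-14), and no KO animal reached the level of any WT animal. Its KO level lay under the table median of 4.57, so the fold is measured against a low signal. The difference was −3.15 in males on HFHS, −2.91 in males on chow and −3.02 in females. Nat1 was at 3.43 ± 0.34 in WT and 2.36 ± 0.22 in KO (SD, n = 10 each), and Nat3, a related gene that was not targeted, was at 3.29 ± 0.24 in WT and 4.21 ± 0.28 in KO. Nat1 and Nat3 lay below that median in nearly all arrays and were outside the genes tested, so they were compared by permuting genotypes within strata. The exact permutation test gave p = 7.14e-05 for each of the 3 genes, the smallest its 28000 arrangements can give. Nat1 was lower in KO in each stratum (−0.70, −1.12 and −1.38 in HFHS males, chow males and females), and Nat3 was higher in each (0.70, 1.14 and 0.83). Which part of each transcript the probe sets cover, inside or outside the deletion, is not given in the sources used here.

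**Figure D1:**
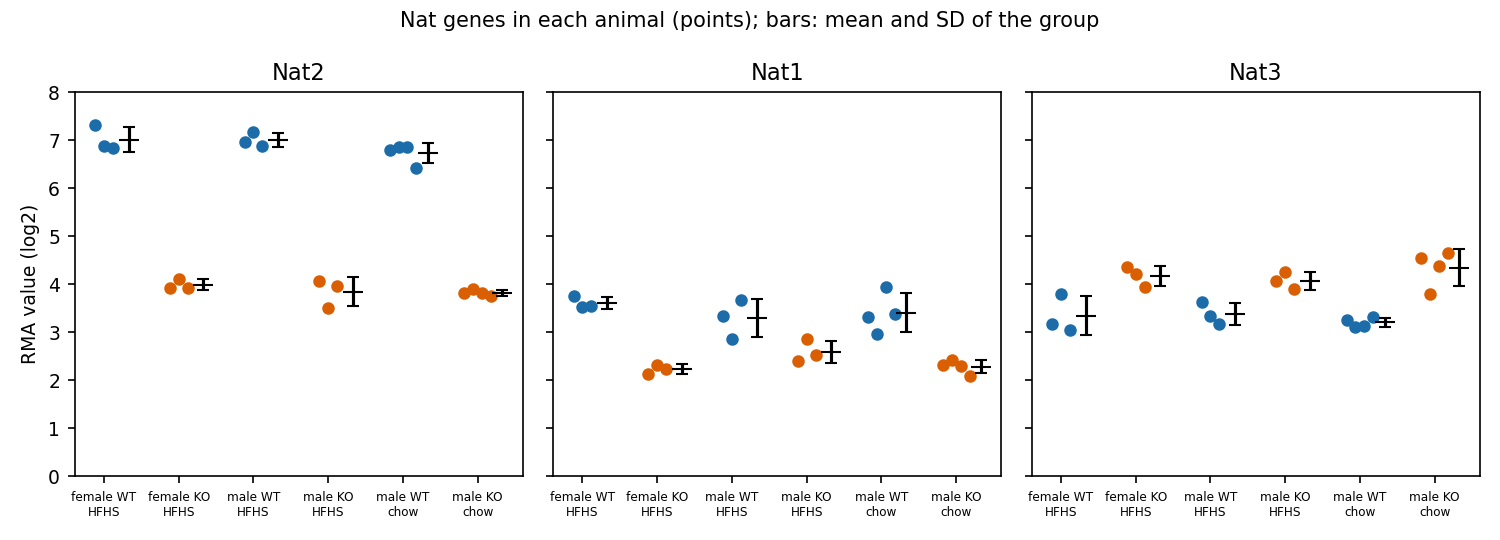
RMA values (log2) of Nat2, Nat1 and Nat3 in each of the 20 animals (points, 1 array per animal; WT blue, KO orange), with the mean and SD of each group as black bars. Nat2 lies between 6.42 and 7.31 in WT and between 3.50 and 4.11 in KO.

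In males on HFHS, which address the effect of genotype under dietary load, 5 genes differed between KO and WT, Nat2 included. Bst2, which encodes the interferon-induced antiviral membrane protein tetherin, fell from 11.04 ± 0.21 in WT to 8.75 ± 0.21 in KO (SD, n = 3 each; 4.89-fold, log2 difference −2.29 ± 0.30 SE, limma adjusted p = 0.00194). Dcpp3, a gene of the salivary demilune cell protein family, fell from 4.88 ± 0.34 to 3.59 ± 0.16 (2.45-fold, adjusted p = 0.0358), a low signal in both. The zinc finger gene Zfp963 rose 2.12-fold, from 5.55 ± 0.08 to 6.64 ± 0.28 (adjusted p = 0.0211), and Ocel1 rose 2.37-fold, from 5.66 ± 0.14 to 6.90 ± 0.33 (adjusted p = 0.0358). The fixed gene lists were compared with all other genes by camera. All 20 measured cholesterol synthesis genes had positive KO minus WT differences (median 0.41, adjusted p = 1.19e-06), with the lanosterol synthase Lss at 0.82 ± 0.27 (SE) and Dhcr7 at 0.64. Of 20 de novo lipogenesis genes, 16 were positive (median 0.18, adjusted p = 0.00639), among them the citrate lyase Acly (0.67) and the liver pyruvate kinase Pklr (0.41). Genes of the endoplasmic reticulum stress list also lay higher (median 0.14, 17 of 23 positive, adjusted p = 0.0245; Sesn2 0.77, Asns 0.61). Oxidative phosphorylation genes lay lower (median −0.10, 44 of 50 negative, adjusted p = 0.00639), as did genes of cytochrome P450 enzymes and xenobiotic receptors (median −0.17, 23 of 30 negative, adjusted p = 0.0245; Cyp2b10 −1.07). Each of these 5 list calls was lost with an estimated correlation (adjusted p = 0.713 with an estimated correlation for each), and no member of the 5 lists passed over all genes or adjusted over the list alone. The mitochondrial fatty acid oxidation list, the process named in the title, was not called (median −0.09, 14 of 21 negative, adjusted p = 0.0734, and adjusted p = 0.713 with an estimated correlation), with the electron transfer flavoprotein Etfa at −0.39 ± 0.13 (SE) and Eci1 at −0.31. The peroxisomal and microsomal fatty acid oxidation list was not called either (median −0.11, adjusted p = 0.0752).

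The HFHS male counts rested on few animals. The 5 genes became 2 without WT 1, WT 3, KO 2 or KO 3. Ocel1 and Dcpp3 failed without any 1 of the 6 animals (adjusted p of at least 0.0569 and 0.0517). Zfp963 passed in 1 of the 6 refits, the one without KO 1 (adjusted p from 0.00940 to 0.154 over the 6), and Bst2 and Nat2 passed in all 6. Among the lists, de novo lipogenesis was lost without KO 1 (adjusted p = 0.608) and oxidative phosphorylation without WT 3 (0.258) or KO 3 (0.402). The P450 list was lost without WT 3 (0.252), KO 1 (0.544) or KO 3 (0.123), and the stress list without WT 2 (0.0687), WT 3 (0.190) or KO 2 (0.152). The cholesterol list kept its call in all 6 refits, but its median of 0.41 was 0.24 without WT 3 (adjusted p = 0.00704) and 0.19 without KO 1 (adjusted p = 0.0484). The lipogenesis median was 0.05 without KO 1 and 0.30 without KO 3, and that of the stress list 0.06 without WT 3. For oxidative phosphorylation it was −0.16 without WT 1 or KO 2, −0.06 without WT 3 and −0.04 without KO 3, and for P450 genes −0.28 without KO 2 and −0.06 without KO 3.

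In males on chow, the same genotype comparison without the dietary load called 5 genes. Zfp963 rose 3.06-fold, from 5.54 ± 0.31 to 7.15 ± 0.16 (SD, n = 4 each; limma adjusted p = 9.86e-06). The zinc finger gene Zfp868 rose 1.85-fold (0.89 ± 0.14 SE, adjusted p = 0.00985) and Mvb12a, a subunit of the ESCRT-I sorting complex, rose 1.52-fold from 7.32 ± 0.05 to 7.93 ± 0.13 (adjusted p = 0.00757). Bst2 fell 3.79-fold, from 11.07 ± 0.11 to 9.15 ± 0.81 (adjusted p = 0.00205), with KO 3 at 10.36 and the other 3 KO animals between 8.72 and 8.77. Lipid synthesis genes lay lower in KO on chow: 17 of 20 de novo lipogenesis genes (median −0.20, adjusted p = 0.000253; Acss2 −0.53, Acly −0.47) and 19 of 20 cholesterol synthesis genes (median −0.24, adjusted p = 0.000133; Dhcr7 −0.46) were negative. With an estimated correlation they gave adjusted p = 0.339 and adjusted p = 0.436. Genes of the endoplasmic reticulum stress list lay higher (median 0.21, 20 of 23 positive, adjusted p = 6.82e-07, and adjusted p = 0.308 with an estimated correlation), with the chaperone-associated Creld2 at 0.77 ± 0.22 (SE) and the disulfide isomerase Pdia4 at 0.34. Acute phase genes lay lower (median −0.23, 20 of 26 negative, adjusted p = 8.79e-06, and adjusted p = 0.394 with an estimated correlation; Saa1 −1.83, Lcn2 −1.53). On that list WT 2 had a mean of 0.72 against −0.31 to −0.60 in the other WT animals, and without WT 2 the median was −0.07 (adjusted p = 0.151). The cholesterol median was −0.15 without WT 2 (adjusted p = 0.0214) and that of the stress list 0.12 without WT 1 (adjusted p = 0.000616). Genes of mitochondrial fatty acid oxidation did not differ (median −0.02, adjusted p = 0.459).

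Of the other lists called in chow males, P450 genes (median 0.10, adjusted p = 0.0123; Fmo5 0.38), male-biased liver genes (0.17, 0.0139; Selenbp2 1.06) and circadian clock genes (0.10, 0.0280; Wee1 0.47) lay higher. Immediate early genes (−0.08, 0.0402), and markers of macrophages (−0.15, 0.0442), lymphocytes (−0.16, 0.0280) and cholangiocytes (−0.26, 0.0204) lay lower. With an estimated correlation these 7 lists gave adjusted p = 0.522, 0.614, 0.424, 0.339, 0.704, 0.308 and 0.308. No member of the 11 lists called in chow males passed over all genes, and only Wee1, a cell cycle kinase under clock control, passed adjusted over the list alone (limma adjusted p = 0.00507). The macrophage markers turned to a median of 0.06 (adjusted p = 0.509) without WT 2, and were also lost without KO 2 (0.273) or KO 3 (0.345). The gene count was 3 without KO 4 and 7 without WT 3. Zfp868 was lost without WT 1, KO 1, KO 3 or KO 4 (adjusted p = 0.0733, 0.0608, 0.0541 and 0.0503) and Mvb12a without KO 4 (0.0503). Each of these 7 lists failed in at least 1 refit without a single animal, with highest adjusted p values, in the order just given, of 0.285 (without WT 2), 0.267 (WT 1), 0.102 (KO 1), 0.133 (KO 1), 0.509 (WT 2), 0.128 (WT 3) and 0.152 (KO 1). Their medians moved as well: P450 genes to 0.16 without WT 1 and 0.07 without WT 2, male-biased genes to 0.05 without WT 1, 0.27 without KO 1 and 0.11 without KO 4, and clock genes to 0.06 without WT 1, WT 3 or KO 3. Immediate early genes went to −0.16 without WT 1, −0.05 without WT 2 and −0.03 without KO 1, macrophage markers to −0.09 without KO 2 and −0.08 without KO 3, and cholangiocyte markers to −0.41 without WT 3.

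In females on HFHS, 7 genes differed between genotypes. Sult1e1, which encodes estrogen sulfotransferase, was the gene with the largest rise, 10.3-fold, from 3.02 ± 0.35 in WT to 6.39 ± 0.75 in KO (SD, n = 3 each; log2 difference 3.37 ± 0.39 SE, limma adjusted p = 0.000325). Its WT level lay under the table median of 4.57, so the fold is measured against a low signal. Bst2 fell 5.52-fold, from 10.89 ± 0.06 to 8.43 ± 0.25 (adjusted p = 0.000432), and the predicted gene C730027H18Rik fell 1.99-fold (adjusted p = 0.0173). Zfp963 rose 2.27-fold (adjusted p = 0.00508), Zfp868 1.98-fold (adjusted p = 0.0171) and Mvb12a 1.54-fold (adjusted p = 0.0221). De novo lipogenesis genes lay higher in KO (median 0.25, 17 of 20 positive, adjusted p = 0.000131), with the desaturase Scd1 at 0.52 ± 0.18 and the acetyl-CoA carboxylase Acacb at 0.50 (SE 0.21), and so did cell cycle genes (median 0.22, 12 of 16 positive, adjusted p = 0.0239; Mki67 0.67). Both list calls were lost with an estimated correlation (adjusted p = 0.899 with an estimated correlation for each), and no member passed over all genes or adjusted over the list alone. For mitochondrial fatty acid oxidation the median was 0.00 (11 of 21 positive, adjusted p = 0.715). Female-biased genes had a median of 0.07 and a mean of −0.00, with the test pointing up (adjusted p = 0.715). The count of 7 fell to 4 without WT 1, WT 2, KO 2 or KO 3 and was 11 without WT 3. Mvb12a failed without any 1 of the 6 animals (adjusted p from 0.0513 to 0.163). Zfp868 was lost without WT 1, WT 2, KO 1 or KO 2 (highest adjusted p = 0.143) and C730027H18Rik without WT 1, WT 2, KO 2 or KO 3 (highest 0.150). Zfp963 was lost without KO 3 (0.0513), and the cell cycle list without WT 1, WT 2, KO 1 or KO 3 (highest 0.151), with a median of 0.15 without WT 1 or KO 3.

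Averaging the genotype difference over the 3 strata gave each stratum equal weight and called 23 genes, 14 higher and 9 lower in KO. Apart from Nat2, the genes with the largest falls were Bst2 (4.67-fold, −2.22 ± 0.16 SE, limma adjusted p = 1.47e-07) and the predicted gene Gm16348 (4.38-fold, adjusted p = 0.00422), whose KO level was low (3.57 to 4.67 by group). Slc18a1, a vesicular monoamine transporter, fell by 0.85 (log2; adjusted p = 0.00132), and the RNA-processing gene Lsm4 fell by 0.70 (adjusted p = 0.0198). Falls were also seen for the SNARE gene Use1 (−0.42, adjusted p = 0.00244), the tRNA methyltransferase-like Trmt9b (−0.42, 0.0440), the non-coding RNA Lncbate1 (−0.73, 0.0313) and Dcpp3 (−0.66, 0.0245). Zfp963 (1.29 ± 0.09 SE, 2.45-fold, adjusted p = 1.47e-07), Zfp868 (0.91, 1.14e-05), Mvb12a (0.59, 1.14e-05) and Ocel1 (0.94, 0.000437) rose. Tecr, which carries out the last step of very-long-chain fatty acid elongation, rose 1.59-fold (adjusted p = 0.00232), from group means of 10.21 to 10.36 in WT to 10.92 to 11.01 in KO. Sult1e1 (1.29, 0.00986), the glycolytic Pgam1 (1.04, 0.0265), the cyclic AMP phosphodiesterase Pde4c (0.68, 0.00580), the deubiquitinase Usp38 (0.60, 0.00986) and Lysmd1 (0.56, 0.0492) also rose. The average of Sult1e1 came mostly from the females, since its difference was 0.53 in males on HFHS and −0.04 in males on chow. Lysmd1 did not rise on chow either (−0.04), and Dcpp3 hardly fell in females (−0.11). Every group mean of Pgam1 (2.50 to 4.42) lay under the table median of 4.57, as did all but 1 of Lncbate1 and all KO means of Slc18a1, so these differences rest on low signal. The rise of Pgam1 in males on HFHS was 0.18. By the reference gene table (GRCm38.p6), 18 of the 22 called genes other than Nat2 lie on chromosome 8, where Nat2 itself lies, and the exceptions were Sult1e1 (chromosome 5), Pgam1 (19), Lysmd1 (3) and Dcpp3 (17).

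**Figure D2:**
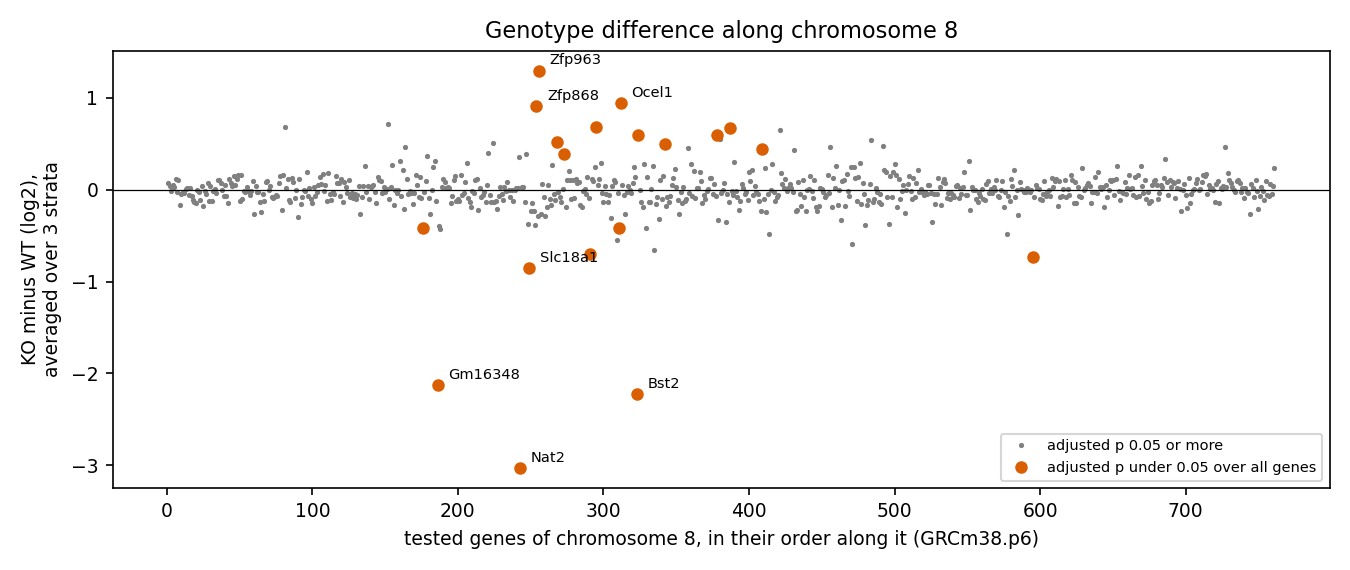
KO minus WT difference (log2, averaged over the 3 strata) of the 761 tested genes of chromosome 8, in their order along it in GRCm38.p6, with genes past adjusted p under 0.05 over all genes in orange and the rest in grey. Of the 18 called genes other than Nat2, 2 lie before it (57 and 67 tested genes away, of 242) and 16 after it (6 to 352 away, of 518).

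Among the lists, genes of endoplasmic reticulum stress lay higher in KO (median 0.11, 20 of 23 positive, adjusted p = 0.000170, and adjusted p = 0.388 with an estimated correlation; Sesn2 0.43, Pdia4 0.18), as did the 4 erythroid markers (median 0.20, adjusted p = 0.0259, and adjusted p = 0.388 with an estimated correlation; the beta-globin gene Hbb-bt 1.22 ± 0.35 SE). De novo lipogenesis genes (median 0.08, 18 of 20 positive, adjusted p = 0.0259) lay higher and oxidative phosphorylation genes lower (median −0.06, 43 of 50 negative, adjusted p = 0.00269), with adjusted p = 0.746 with an estimated correlation for both. The lipogenesis average merged strata called in opposite directions, higher in females (0.25) and in males on HFHS (0.18) and lower in males on chow (−0.20), so it describes no shared shift. Hbb-bt was the only member of the 4 lists to pass adjusted over the list alone, and none passed over all genes. Neither direction was favoured by mitochondrial fatty acid oxidation genes (median −0.03, adjusted p = 0.208). The 20 measured neighbours of the Nat genes on chromosome 8 were not shifted as a group (median −0.11, adjusted p = 0.124), while 4 rose and 3 fell adjusted over the list alone and 1 rose (Tm6sf2, involved in lipid loading of secreted lipoproteins, 0.52) and 1 fell (Slc18a1) over all genes. The count of 23 was 15 without female WT 2 or female KO 2. Without single animals, the lipogenesis list was lost in 8 of 20 refits (highest adjusted p = 0.439, without male KO HFHS 1), the erythroid list in 5 of 20 (0.161, without male KO HFHS 3) and oxidative phosphorylation in 2 of 20 (0.0590 and 0.114, without male HFHS WT 3 and KO 3). Of the named genes Lysmd1, Trmt9b, Lncbate1, Dcpp3, Pgam1 and Lsm4 passed in 4, 3, 6, 11, 12 and 16 of 20. Among HFHS males, the lipogenesis median was 0.05 without WT 3, 0.02 without KO 1 and 0.14 without KO 3, the erythroid median 0.32 without KO 1 and 0.08 without KO 3, and that of oxidative phosphorylation −0.04 without WT 3.

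The interaction of genotype and diet in males asked whether the genotype difference depended on the diet. No gene passed by limma, 800 had an unadjusted p under 0.05 against 694 expected by chance. A limma fit with a variance trend and robust moderation also called 0, as did the fit of all 22 arrays with a batch term. Among the genes with the smallest p, none of which passed, were Stx12 (0.89 ± 0.17 SE), Creb3l2 (1.01 ± 0.23), Setdb2 (−1.08 ± 0.25) and Larp1b (−0.68 ± 0.16), each with adjusted p = 0.718. As groups, lipid synthesis genes had a more positive KO minus WT difference on HFHS than on chow: all 20 cholesterol synthesis genes (median 0.64, adjusted p = 3.93e-10; Dhcr7 1.10, Lss 1.14, Sqle 2.36) and 17 of 20 lipogenesis genes (median 0.43, adjusted p = 4.84e-06; Acly 1.14, Acss2 1.01, Pklr 0.64). Both were lost with an estimated correlation (adjusted p = 0.285 with an estimated correlation for each). None of their members passed over all genes, and 2 cholesterol synthesis genes (Dhcr7 and Lss) and 3 lipogenesis genes (Acly, Acss2 and Pklr) passed adjusted over the list alone. Acute phase genes (median 0.48, adjusted p = 0.000181), immediate early genes (median 0.20, adjusted p = 0.00959; Junb 0.81, Ier3 0.79) and macrophage markers (median 0.31, adjusted p = 0.00950) were also more positive on HFHS. P450 genes were more negative (median −0.30, 25 of 30 negative, adjusted p = 0.000295). With an estimated correlation these 4 gave adjusted p = 0.706, 0.285, 0.753 and 0.544. Within the acute phase list the iron hormone gene Hamp (−2.92) went against the amyloid P gene Apcs (1.62), and both passed adjusted over the list alone, as did Junb and Ier3. No such difference was seen for mitochondrial fatty acid oxidation (median −0.03, adjusted p = 0.356). A single gene was called without KO HFHS 1. Immediate early genes were lost without WT HFHS 1 (0.129) or KO HFHS 2 (0.186), P450 genes without KO HFHS 1 (0.0575), and macrophage markers without WT HFHS 1 (0.0508), KO HFHS 1 (0.159), WT chow 2 (0.400) or KO chow 3 (0.0547). The medians were 0.20 without KO HFHS 1 for lipogenesis (adjusted p = 0.0150), 0.30 and 0.14 without WT chow 2 for acute phase genes and macrophage markers, and 0.10, 0.40 and 0.09 without WT HFHS 1, KO HFHS 3 and WT chow 3 for immediate early genes.

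The interaction of genotype and sex on HFHS asked the same of the sexes. No gene passed by limma, 717 had an unadjusted p under 0.05 against 694 expected by chance. A limma fit with a variance trend and robust moderation called 0, and so did the fit of all 22 arrays with a batch term. C730027H18Rik (−1.33 ± 0.23 SE, adjusted p = 0.205) and Sult1e1 (2.84 ± 0.55, adjusted p = 0.354) had the smallest p, so the rise of Sult1e1 in females was not shown to differ from that in males. Gm11189 (1.22), Olfr978 (0.90) and Trav12-2 (−1.11) followed, each at adjusted p = 0.933. All 20 cholesterol synthesis genes had a KO minus WT difference that was more negative in females than in males (median −0.45, adjusted p = 0.000290; Lss −0.97), and 23 of 30 P450 genes had one that was more positive (median 0.19, adjusted p = 0.0273; Cyp2c40 1.45). Both gave adjusted p = 0.918 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. The mitochondrial fatty acid oxidation list had a median of 0.10 (adjusted p = 0.152). In 3 lists not called the signs differed, such as the acute phase list with a median of −0.13 and a mean of 0.09. The gene count was 1 without male WT 1 and 2 without male KO 1 or male KO 2. The cholesterol list was lost without female WT 1 (median −0.19, adjusted p = 0.131) or male KO 1 (−0.16, 0.110), with medians of −0.25 without male WT 3 and −0.68 without male KO 2, and the P450 list without female WT 1 (0.0511), female WT 2 (0.299), female KO 1 (0.0670), male WT 3 (0.189), male KO 1 (0.343) or male KO 3 (0.0535). The P450 median was 0.12 without female WT 2 or male KO 1 and 0.30 without male KO 2.

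The diet comparison in WT males spanned both batches and was fitted with a batch term, which the pair of animals hybridised in both batches made estimable. At a within-animal correlation of 0.228, the term also drew on differences between these 2 animals and others of their groups. The term passed the threshold in 212 genes, but the batch differences of these 2 animals hardly agreed across genes (r = 0.0716), so the correction of single genes is uncertain. Differences given for diet are those of that fit and include the batch correction. Cyp2b13, a P450 gene with female-predominant expression in mouse liver, rose 17.9-fold on HFHS (4.16 ± 0.68 SE), from 3.57 ± 0.61 on chow (SD, n = 4) to 8.17 ± 0.80 on HFHS (SD, n = 3, Batch1 arrays), so its fold is against a chow level under the table median of 4.57. The male-predominant fatty acid hydroxylase genes Cyp4a12a and Cyp4a12b fell 9.08-fold and 8.30-fold (−3.18 ± 0.52 and −3.05 ± 0.49 SE). Gnl3, encoding nucleostemin, fell 2.22-fold and the chemokine gene Ccl9 1.94-fold. These 5 genes were all that passed, each at limma adjusted p = 0.0144. Cholesterol synthesis genes lay lower on HFHS (median −0.59, 17 of 20 negative, adjusted p = 4.49e-09; Tm7sf2 −0.95, Stard4 −0.69), as did de novo lipogenesis genes (median −0.23, 12 of 20 negative, adjusted p = 0.00241; Acss2 −1.20, Acacb −1.05), and 4 members of each fell adjusted over the list alone. Male-biased liver genes lay lower (median −0.32, 16 of 20 negative, adjusted p = 7.52e-05), 2 of them (Cyp4a12a and Cyp4a12b) over all genes, and 3 fell and 1 rose adjusted over the list alone. All 22 macrophage markers were positive (median 0.31, adjusted p = 0.00105; Tyrobp 0.62), and 14 of 16 cell cycle genes were (median 0.31, adjusted p = 0.00241). Small shifts down were seen for oxidative phosphorylation (median −0.09, adjusted p = 0.0339) and endoplasmic reticulum stress genes (median −0.12, adjusted p = 0.0339), and none of the members of these 4 lists passed over all genes or adjusted over the list alone. All 7 list calls were lost with an estimated correlation (adjusted p = 0.710 with an estimated correlation for each). Mitochondrial fatty acid oxidation genes had a median of 0.01 (adjusted p = 0.754), and in the ketogenesis, gluconeogenesis and Nat neighbour lists, none called, the median, mean and test differed in sign.

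The diet calls in WT males depended on single animals and on the batch term. No gene was called without WT HFHS 1, 1 of the 2 animals that link the batches, or without WT chow 4 (Cyp2b13 adjusted p = 0.764 and 0.0608). Without WT HFHS 1 the fall of Cyp4a12a was −1.36 in place of −3.18 (adjusted p = 0.810). Without WT chow 2 the count was 8, the Batch2 arrays alone called 2, and 480 were called with no batch term. Oxidative phosphorylation then had a median of 0.38 in place of −0.09, with the values of both animals hybridised in both batches lower in Batch2 than in Batch1 (0.09 against −0.28 for WT 1 and −0.02 against −0.47 for KO 3).

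**Figure D3:**
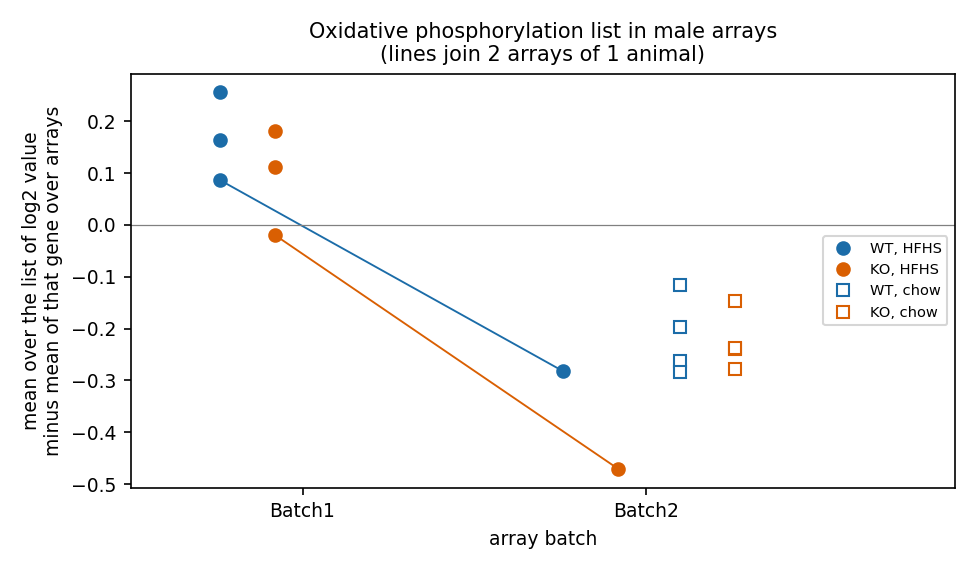
Mean over the oxidative phosphorylation list of each gene's log2 value minus its mean over all arrays, for each male array by batch (WT blue, KO orange; HFHS filled circles, chow open squares), with lines joining the 2 arrays of 1 animal. Both animals measured in both batches fall, from 0.09 to −0.28 and from −0.02 to −0.47, and the 8 chow arrays lie between −0.28 and −0.12.

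Single lists called for diet in WT males were lost without WT HFHS 1 (male-biased genes, adjusted p = 0.127; cell cycle, 0.202; oxidative phosphorylation, 0.167) and without WT chow 3 (macrophage markers, 0.0534). The oxidative phosphorylation list was also lost without WT HFHS 2, WT chow 1 or WT chow 3 (highest adjusted p = 0.378), and the endoplasmic reticulum stress list without WT HFHS 2, WT HFHS 3 or WT chow 2, 3 or 4 (highest 0.151). The medians of male-biased genes were −0.21 without WT HFHS 1 and −0.53 without WT chow 1, those of macrophage markers 0.50 without WT chow 2 and 0.14 without WT chow 3. Lipogenesis genes had −0.45 without WT HFHS 1 and oxidative phosphorylation −0.05 without WT chow 1. Stress genes had −0.35, −0.08, −0.19 and −0.06 without WT HFHS 1, WT HFHS 3, WT chow 1 and WT chow 2.

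In KO males the same diet comparison called 28 genes, 15 higher and 13 lower on HFHS. Cyp2b9, another P450 gene with female-predominant expression, rose 41.7-fold (5.38 ± 1.01 SE, limma adjusted p = 0.0349), from 5.48 ± 1.96 on chow (SD, n = 4) to 11.27 ± 0.89 on HFHS (SD, n = 3). Lcn2, the siderophore-binding acute phase protein lipocalin 2, rose 15.7-fold (adjusted p = 0.0476), from 7.26 ± 0.17 to 11.23 ± 0.46. Hamp, which encodes the iron-regulating hormone hepcidin, fell 15.6-fold in the fit with the batch term (−3.97 ± 0.72 SE, limma adjusted p = 0.0344). The means of 1 array per animal, 13.17 ± 0.08 on chow and 10.01 ± 2.30 on HFHS, lay closer together. The fit also held a second array of KO HFHS 3, the animal with the lowest Hamp (7.76 in Batch1, 8.16 in Batch2). WT HFHS 1, the other animal measured in both batches, also read higher in Batch2 (12.93 against 12.86). A higher reading in Batch2 would narrow the gap between HFHS and chow, yet the fit gave a wider gap than the means of 1 array per animal. The batch term for Hamp was thus not set by the repeat arrays of these 2 animals alone. The size of the fall and its SE are therefore uncertain, and the 15.6-fold fall may be too large. Tfrc, the transferrin receptor, rose 2.41-fold (adjusted p = 0.0476). The fatty acid binding protein gene Fabp4 rose 3.38-fold (adjusted p = 0.0476), and Rdh9 (2.63-fold, 0.00917), Tgfbi (2.24-fold, 0.0328), Isg20 (2.12-fold, 0.0349) and Dsg1c (3.76-fold, 0.0316) rose with the predicted genes 9030619P08Rik (5.05-fold) and Gm15318 (2.48-fold). Cyp4a12a fell 14.3-fold (−3.84 ± 0.52 SE, adjusted p = 0.00513) and Cyp4a12b 9.46-fold (adjusted p = 0.00917). Acot1, an acyl-CoA thioesterase induced through PPARα, fell 4.78-fold (adjusted p = 0.0476), and Creld2 (2.69-fold, 0.0476), Cyp3a44 (2.60-fold, 0.0476), the glucose-responsive Txnip (2.41-fold, 0.0476), the elongase Elovl3 (2.29-fold, 0.0389), the carboxylesterase Ces1e (2.23-fold, 0.0344) and B4galt2 (1.91-fold, 0.0476) fell. Without KO HFHS 3, Hamp fell only 4.01-fold (adjusted p = 0.249), Cyp3a44 by 0.67 (log2; 0.508), and Dsg1c and Gm15318 rose by 1.27 (0.321) and 0.62 (0.405).

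By list, acute phase genes lay higher in KO males on HFHS (median 0.54, 23 of 26 positive, adjusted p = 3.44e-08), with 1 called up (Lcn2) and 1 down (Hamp) over all genes, and 13 up and 1 down adjusted over the list alone. All 22 macrophage markers were positive (median 0.56, adjusted p = 1.62e-08; Mpeg1 1.27, Itgam 0.83), 4 of them passing adjusted over the list alone and none over all genes, and 19 of 22 stellate cell and collagen markers were (median 0.33, adjusted p = 0.00181, none passing either way). Peroxisomal and microsomal fatty acid oxidation genes lay lower (median −0.24, 15 of 20 negative, adjusted p = 0.00243), with Acot1 alone past the threshold over all genes, and 7 down (Cyp4a10 at −1.38 ± 0.33 SE among them) and 1 up (Abcd2 at 1.80) adjusted over the list alone. Oxidative phosphorylation genes (median −0.14, 45 of 50 negative, adjusted p = 8.45e-06, none passing either way), male-biased genes (median −0.40, 17 of 20 negative, adjusted p = 8.98e-06; 3 down both over all genes and adjusted over the list alone) and endoplasmic reticulum stress genes (median −0.21, 18 of 23 negative, adjusted p = 0.000570; 1 down over all genes and 3 adjusted over the list alone) lay lower too. P450 genes had a median of −0.20 (adjusted p = 0.0199), with none called over all genes and 1 up and 3 down adjusted over the list alone. With an estimated correlation the P450 list gave adjusted p = 0.732, the stellate list adjusted p = 0.378 and the other 6 lists adjusted p = 0.370. Mitochondrial fatty acid oxidation genes had a median of −0.11 (13 of 21 negative, adjusted p = 0.368). The 28 genes became 3 without KO HFHS 3, the other animal that links the batches, 46 without KO HFHS 1, and 5, 7 and 10 without KO chow 2, 3 and 4. Without KO HFHS 3, Lcn2 was at adjusted p = 0.286 and Cyp2b9 at 0.159. Cyp4a12a and Cyp4a12b passed in all 7 refits without single animals, while Lcn2, Tfrc, Fabp4, Acot1 and Txnip passed in 1 of 7 and B4galt2 in 0 of 7. Creld2 and Elovl3 passed in 2 of 7 (highest adjusted p = 0.365 and 0.205), Ces1e, Cyp3a44, Gm15318 and Hamp in 3, Cyp2b9, Isg20 and Tgfbi in 4, 9030619P08Rik in 5, and Rdh9 and Dsg1c in 6. Without that animal the peroxisomal list had a median of 0.01 (adjusted p = 0.996) and the oxidative phosphorylation (0.261), stress (0.268) and P450 lists (0.101) were lost, the last also without KO HFHS 1 (0.108) or KO chow 1 (0.0965). Male-biased genes kept their call, with a median of −1.23 without KO HFHS 3 (adjusted p = 3.01e-11) and −0.63 without KO chow 1 (adjusted p = 2.97e-07). Acute phase, oxidative phosphorylation and stress genes had medians of 0.30, −0.08 and −0.12 without KO HFHS 3, and P450 genes −0.12 without KO HFHS 1 and −0.08 without KO chow 1. The Batch2 arrays alone called 12 genes, and 993 were called with no batch term, where oxidative phosphorylation genes had a median of 0.29.

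The comparison of females with males on HFHS, all within Batch1, gave the largest numbers of calls. In WT, 195 genes passed, 110 higher and 85 lower in females. Outside the sex chromosomes (Xist 6.45 higher, Eif2s3y −4.65 and Uty −4.26), hydroxysteroid sulfotransferase genes were among those higher in females. Sult2a2 was 75.5-fold higher in females (9.57 ± 0.88 against 3.33 ± 0.71, SD, n = 3 each; limma adjusted p = 4.25e-08), Sult2a1 53.6-fold and Sult2a3 31.1-fold (adjusted p = 3.08e-06 for each). Cyp3a16 (27.4-fold, 3.08e-06), A1bg (22.6-fold, 0.000165), the transporter gene Slc22a26 (22.2-fold, 4.99e-07), Sult3a1 (21.5-fold, 1.04e-05), Cyp2c69 (11.4-fold, 2.62e-06) and Sult3a2 (10.1-fold, 0.0306) were higher too. Of these genes only Slc22a26 and Cyp2c69 had a male mean above the table median of 4.57, so the other folds are against a low signal and their order is uncertain. Lower in females were the organic anion transporter Slco1a1 (−4.42 ± 0.93 SE, adjusted p = 0.0199), the steroid hydroxylase Cyp2d9 (−4.41 ± 0.32, 6.58e-08), Elovl3 (−4.10 ± 0.20, 1.50e-10), the major urinary protein gene Mup21 (−3.88, 2.49e-06), Cyp4a12a (−3.60, 1.44e-05), Obp2a (−3.58, 0.0299), Zfp979 (−3.54, 0.00132) and Omd (−2.92, 4.29e-05). Of these only Cyp2d9 and Elovl3 had a female mean above that median, so the other differences are against a low signal and their order is uncertain. Of 20 female-biased genes 14 were called higher over all genes and 17 adjusted over the list alone (median 1.73, adjusted p = 1.40e-28), and of 20 male-biased genes 11 were called lower over all genes and 16 adjusted over the list alone (median −1.55, adjusted p = 1.53e-27). Both held with an estimated correlation (adjusted p = 0.000491 and 0.00891).

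Lists with weaker shifts between WT females and males were lost with an estimated correlation. All 20 cholesterol synthesis genes were positive (median 0.51, adjusted p = 2.42e-05, and adjusted p = 0.466 with an estimated correlation; 2 passed adjusted over the list alone, none over all genes). Lipid droplet and uptake genes lay lower (median −0.23, adjusted p = 0.000477), with the fat storage gene Fitm1 at −1.35 and Vldlr at 1.15 past the threshold over all genes and 1 higher and 4 lower adjusted over the list alone. Cell cycle genes (median −0.39, 0.000533; 1 higher and 3 lower adjusted over the list alone, none over all genes) and erythroid markers (median −0.75, 0.0209; Alas2 −1.97, which passed both ways) lay lower, and clock genes higher (median 0.28, 0.00794; Per3 0.80 and Tef 0.78 over all genes, 2 higher and 1 lower adjusted over the list alone). These 4 lists gave adjusted p = 0.331 with an estimated correlation. Conjugation and antioxidant genes lay lower (median −0.24, adjusted p = 0.00258, and adjusted p = 0.471 with an estimated correlation), with the thiopurine methyltransferase gene Tpmt at −1.29 over all genes and 1 higher and 1 lower adjusted over the list alone. Mitochondrial fatty acid oxidation genes had a median of 0.11 (adjusted p = 0.203). The 195 genes became 69 without female WT 2, 97, 121 and 103 without male WT 1, 2 and 3, and 102 when only these 2 groups were fitted. Slco1a1, Obp2a and Sult3a2 passed in 2, 1 and 1 of 6 refits without single animals (highest adjusted p = 0.110, 0.127 and 0.101). The erythroid list was lost without female WT 2 (0.0960) or male WT 3 (0.0661), and the cholesterol list without female WT 1 (0.0570). The medians were then −0.46 and −0.42 for erythroid markers and 0.27 for cholesterol synthesis, while cell cycle genes had −0.22 without male WT 2 and conjugation genes −0.16 without female WT 2. Sult3a2 was higher by 2.11 (log2) without female WT 1, in place of 3.34.

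**Figure D4:**
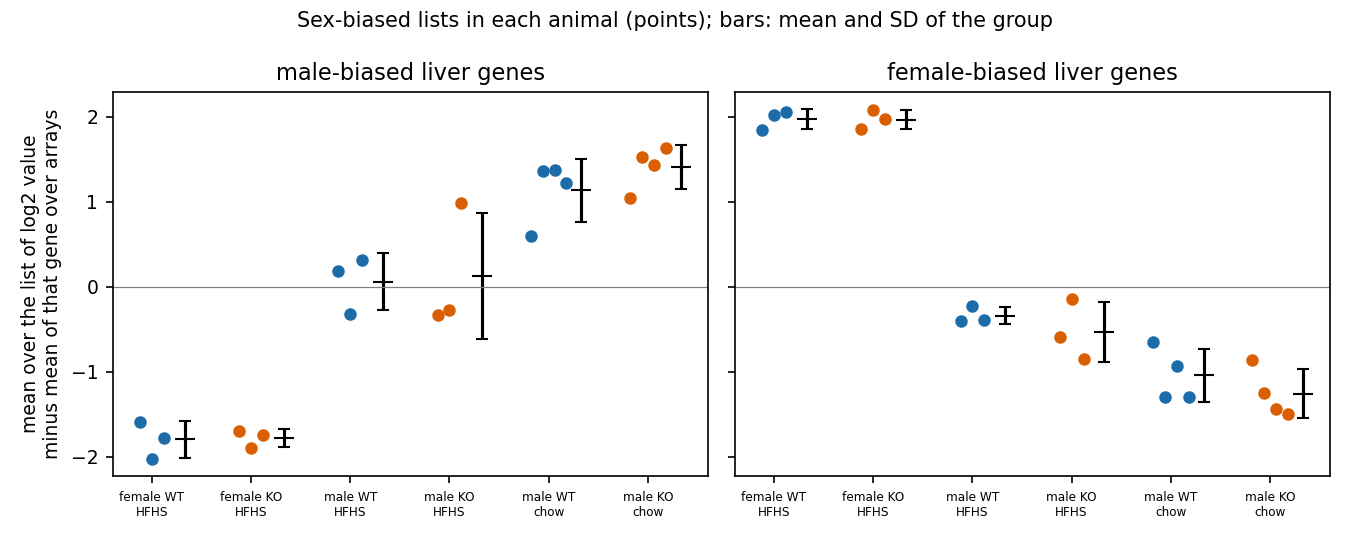
Mean over the male-biased and female-biased lists of each gene's log2 value minus its mean over all arrays, in each of the 20 animals (points, 1 array per animal; WT blue, KO orange), with the mean and SD of each group as black bars. On the male-biased list the females lie between −2.02 and −1.59, the HFHS males between −0.33 and 0.98 and the chow males between 0.59 and 1.63.

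In KO animals, 148 genes differed between the sexes on HFHS, 83 higher and 65 lower in females. Sult2a2 rose to 10.37 ± 0.05 in females against 2.58 ± 0.47 in males (SD, n = 3 each; log2 difference 7.78 ± 0.44 SE, limma adjusted p = 1.07e-09), Sult2a1 differed 179-fold and Cyp3a16 75.8-fold (adjusted p = 6.86e-08 for each), Sult2a3 73.0-fold (1.11e-07) and Cyp2b13 25.3-fold (8.71e-05). The male means of Sult2a1, Sult2a2, Sult2a3 and Cyp3a16, 2.36 to 2.92, lay under the table median of 4.57, so the size of their folds is set by a low signal. Hamp2, a hepcidin paralogue, was 18.9-fold higher in females (11.98 ± 0.03 against 7.75 ± 1.94, adjusted p = 0.00611), and Slc22a26 (4.23), Cyp2c69 (3.89) and Cyp2c40 (3.65) were higher too. Lower in females were Slco1a1 (−4.42 ± 0.93 SE, adjusted p = 0.0200), Cyp2d9 (−3.58, 1.00e-06), the alpha-1-antitrypsin gene Serpina1e (−3.25, 0.0182), Mup21 (−3.14), Cyp4a12a (−3.13), Elovl3 (−3.07 ± 0.20, 1.57e-08) and Omd (−2.88), where Slco1a1, Mup21, Cyp4a12a and Omd had female means under that median, with Xist (7.00), Eif2s3y (−4.99) and Uty (−3.85) marking sex. Female-biased genes (median 1.98, adjusted p = 4.01e-39; 13 higher over all genes, 18 adjusted over the list alone) and male-biased genes (median −1.79, adjusted p = 1.91e-33; 12 lower over all genes, 14 adjusted over the list alone) held with an estimated correlation (adjusted p = 8.53e-05 and 0.00374). Of 21 mitochondrial fatty acid oxidation genes, 20 were higher in KO females than in KO males (median 0.19, adjusted p = 0.000113, and adjusted p = 0.149 with an estimated correlation), with Etfa at 0.40 ± 0.13 and Crat at 0.50 ± 0.18 (SE), none passing over all genes or adjusted over the list alone. Peroxisomal and microsomal fatty acid oxidation genes lay higher (median 0.22, adjusted p = 8.20e-05, and adjusted p = 0.149 with an estimated correlation), with the thioesterase genes Acot3 (2.05) and Acot4 (1.29) passing over all genes and 6 adjusted over the list alone, and had a median of 0.13 without male KO 3 (adjusted p = 0.00978). Whether these fatty acid oxidation differences were larger in KO than in WT is the genotype by sex interaction, in which the mitochondrial list was not called.

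Ketogenesis genes lay higher in KO females than in KO males (median 0.18, adjusted p = 0.00914, and adjusted p = 0.144 with an estimated correlation; Bdh1 and Txnip passed adjusted over the list alone, none over all genes), and so did P450 genes (median 0.13, adjusted p = 0.00111, and adjusted p = 0.422 with an estimated correlation; Cyp2c40, Cyp2a22 and Cyp2c68 over all genes, 8 higher and 2 lower adjusted over the list alone). Endoplasmic reticulum stress genes (median −0.27, adjusted p = 5.89e-06, and adjusted p = 0.149 with an estimated correlation; 3 lower adjusted over the list alone, none over all genes) and erythroid markers (median −1.30, adjusted p = 0.00111, and adjusted p = 0.107 with an estimated correlation; Alas2 over all genes at 0.000746, 2 lower adjusted over the list alone) lay lower. Lipid droplet genes lay lower (median −0.24, adjusted p = 0.00161, and adjusted p = 0.289 with an estimated correlation), with Fitm1 (−0.98) and Fabp4 (−1.47) passing over all genes and 1 higher and 3 lower adjusted over the list alone. The 148 genes became 93, 81 and 94 without female KO 1, 2 and 3, and 52 when only these 2 groups were fitted. Slco1a1 and Serpina1e passed in 2 and 1 of 6 refits without single animals (highest adjusted p = 0.0815 and 0.0696). The ketogenesis list was lost without female KO 2 (0.0917) or male KO 3 (0.139), and the P450 and lipid droplet lists without male KO 1 (0.0955 for both). Medians were 0.33 and 0.28 without female KO 1 and male KO 1 for ketogenesis, and 0.07, 0.24 and 0.21 without male KO 1, 2 and 3 for P450 genes. They were −0.15 without male KO 1 for lipid droplet genes and −0.85 without male KO 3 for erythroid markers.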

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

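Of the tests in this part, those chosen only after the result was seen were the other splits of the animals, the share of calls on chromosome 8, the probe mismatch, the decline with distance from Nat2, the batch and diet tests of the oxidative phosphorylation list and those of low hepcidin.

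In the chow groups of 4, 67 genes and 21 lists were checked in 2 groups. Of these 176 sets of 4 values, 8 held a value far from the other 3 animals, against 8.80 expected by chance. Among WT animals these values were Nat2 in WT 4 (6.42, others 6.79 to 6.85), Sult1e1 in WT 3 (3.00, others 2.79 to 2.81), Pde4c in WT 3 (5.01, others 5.48 to 5.55), Lcn2 in WT 2 (11.85, others 7.43 to 7.96) and Sult2a1 in WT 1 (4.40, others 2.18 to 2.30). Among KO animals they were Bst2 in KO 3 (10.36, others 8.72 to 8.77), Dsg1c in KO 4 (4.54, others 5.61 to 5.72) and the mean of the circadian clock list in KO 2 (−0.00227, others 0.102 to 0.110). Groups of 3 were too small for this check.

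The genotype difference of 8 gene lists differed between diets or sexes in the test of the interaction. Between diets in males, HFHS minus chow, the medians were 0.43 for de novo lipogenesis, 0.64 for cholesterol synthesis, −0.30 for cytochrome P450 genes, 0.48 for the acute phase response, 0.20 for immediate early genes and 0.31 for macrophage markers. Between sexes on HFHS, females minus males, they were −0.45 for cholesterol synthesis and 0.19 for P450 genes. None of the 8 was kept with an estimated correlation (lowest adjusted p = 0.285 with an estimated correlation).

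Each comparison was repeated on other splits of the same animals. For genes, the real split was the only one of 35 with as many calls in males on chow (5, highest other 1), in the diet comparison of WT males (5, highest other 2) and in that of KO males (28, highest other 2). The same held for 1 of 100 splits of the averaged genotype difference (23, highest other 2). The share was thus under 0.05 for these 4 counts, without adjustment over the comparisons. The 2 genotype counts include the targeted gene Nat2. In the 2 diet comparisons only the real split followed the batches. There the splits cannot tell a diet difference from an imperfect batch correction. For the genotype by diet and genotype by sex interactions, 100 of 100 splits gave at least the 0 genes of the real one (highest other 4 and 10), which a real count of 0 makes certain, so these splits decide nothing. With 3 animals on each side the 10 splits are too few for a share under 0.05. There, as many genes as the real split were called in 1 for females (7, highest other 0), in 1 for the sex difference in WT (195, highest other 0), in 1 for that in KO (148, highest other 0) and in 2 for males on HFHS (5, highest other 17).

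For the counts of lists, chance could not be excluded in 6 comparisons. As many lists as in the real split were called in 2 of 35 splits for males on chow (11, highest other 11), 70 of 100 for the averaged difference (4, highest other 12), 66 of 100 for genotype by diet (6, highest other 15), 90 of 100 for genotype by sex (2, highest other 12), 7 of 35 for diet in WT (7, highest other 13) and 21 of 35 for diet in KO (8, highest other 14). The 10 splits of the remaining comparisons are too few for a share under 0.05. As many lists were called in 9 for males on HFHS (5, highest other 12), 4 for females (2, highest other 7), 4 for the sex difference in WT (8, highest other 8) and 7 for that in KO (9, highest other 15).

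The first pattern weighed was the crowding of genotype calls on chromosome 8, which held 18 of the 22 genes called in the averaged difference other than Nat2, against 5.49% of tested genes (one-sided Fisher's exact p = 9.92e-20), so loss of the enzymes acting anywhere in the genome was excluded as the sole cause. DNA of the donor strain kept around the targeted locus was in line with the test set for it, since the KO minus WT differences of chromosome 8 genes that were not called had a mean correlation of 0.182 between strata, against at most 0.0314 for any other chromosome, and that correlation declined from 0.309 in the 100 tested genes nearest Nat2 on either side to 0.0174 beyond 400. The calls lay on both sides, 2 before Nat2 (of 242 tested genes) and 16 after it (of 518), and this difference was not tested. The decline was not tested for each side alone. No probe sequences were examined. A mismatch with donor sequence was assumed to lower the KO signal. By direction alone it would not account for the 11 genes higher in KO, and it stayed open for the 7 lower ones. A different stretch of donor DNA in single KO animals was not borne out over all KO animals (permutation p = 0.339). That test averages over animals and genes, so it cannot exclude a shorter stretch in 1 animal. KO HFHS male 3 showed low shares of the other KO animals' difference in the called genes farthest after Nat2. They were 0.20 for Usp38, 0.37 for Tecr, −0.18 for Cacna1a and 0.26 for Lncbate1. Just before them Bst2, Mvb12a and Ap1m1 had 1.16, 1.13 and 0.75. Nearer Nat2, however, Tm6sf2 and Use1 were also low in that animal (0.36 and 0.44). Lncbate1 was low in KO chow males 2 and 3 as well (−0.02 and 0.24). The low shares were thus not confined to 1 stretch or 1 animal. They were seen afterwards and were not tested. An effect of the deletion itself on its neighbours stayed open, as the labels name the strain C57BL/6 and WT littermate controls but not how the targeted line was made or bred to that strain.

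The second pattern was the higher level of oxidative phosphorylation genes on HFHS when no batch term was fitted. Array batch was in line with the test set for it, because the list's mean was lower in Batch2 than in Batch1 by 0.369 and 0.451 in the 2 animals hybridised in both. Within Batch2 the mean of the HFHS arrays was not higher than that of the chow arrays (−0.157, 2 against 8 arrays). Both HFHS arrays (−0.28 for WT 1 and −0.47 for KO 3) lay under the chow mean of −0.22 (SD 0.06). These values argue against a rise with diet of the size seen without a batch term. A small rise stayed open, as WT 1 lay at the lower edge of the chow range and there was 1 animal per genotype. Over the genes called for diet without a batch term, the share of the diet difference that the animal of the other genotype showed between batches was taken. Its median was 0.325 in WT males (quartiles 0.018 to 0.684), with 77.5% of genes in the same direction. That passed the share set beforehand for batch, but covered only part of the difference. In KO males the median was 0.206 (quartiles −0.106 to 0.563), which left batch open there.

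The third pattern was low hepcidin in KO males on HFHS, with Hamp at 10.01 ± 2.30 in KO and 12.90 ± 0.21 in WT (SD, n = 3 each; exact permutation p = 0.1, limma adjusted p = 0.227) and Hamp2 at 7.75 ± 1.94 and 10.89 ± 0.34. With 3 animals on each side, 0.1 is the smallest p that the permutation test can give, so it could not pass the threshold. Tfrc differed by 0.97 and Hbb-bt by 2.33, neither past the threshold, and these genes were chosen after their values had been seen. A failed array was excluded for KO 3, the animal with the lowest Hamp, since its second array lay only 0.40 from the first. The median over 75 genes of bile acid, gluconeogenesis and conjugation lists was −0.0496 (quartiles −0.15 to 0.06), so these genes showed no large fall. Against the Hamp difference of −2.89, these values argue against dilution of liver RNA by blood as the source of the low Hamp. A small share of blood could raise Hbb-bt without such a fall, so the test cannot exclude blood in the samples. The biological explanation that loss of the enzymes lowers hepcidin on HFHS could not be told from differences between single animals with n = 3.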

How the results depend on the processing

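Of the tests in this part, those without 2 of the 3 animals apart on the third component (female WT 2 and male KO 3 on HFHS; chow WT 2 was left out only singly) were chosen only after the result was seen, as were those of lists without single animals, with other batch terms or arrays, with repeats averaged and after normalisation again.

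For males on HFHS (5 genes) the count was 3 without a filter, 2 with only the groups compared, 8 with 22 arrays and batch term, 3 with repeats averaged, 1 without the 2 animals apart and 2 to 6 without single animals. For males on chow (5) it was 2 with only the groups compared, 8 with repeats averaged and 3 to 7 without single animals. For females (7) it was 4 without the 2 animals apart and 4 to 11 without single animals, and for the averaged difference (23) 15 to 25. The interactions with diet and sex gave 0 to 1 and 0 to 2 without single animals. Diet in WT males (5) gave 8 with the stricter filter, 2 with trend and robust moderation, 480 with no batch term, 93 with repeats averaged and no batch term, 2 with Batch2 arrays alone, 3 without the 2 animals apart and 0 to 8 without single animals. Diet in KO males (28) gave 11 without a filter, 993 with no batch term, 591 with repeats averaged and no batch term, 12 with Batch2 arrays alone, 3 without the 2 animals apart and 3 to 46 without single animals. The sex difference in WT (195) gave 102 with only the groups compared, 103 without the 2 animals apart and 69 to 175 without single animals, and that in KO (148) gave 52 with only the groups compared and 81 to 160 without single animals. The 62 list calls became 4 with an estimated correlation and 9 by fry. The cause was not tested, except that fits without animals or groups hold fewer arrays. The Batch2 fit held 1 HFHS animal per genotype, assumed to vary like the other groups.

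Oxidative phosphorylation reversed with no batch term, to 0.38 in WT and 0.29 in KO males, and with repeats averaged and no batch term, to 0.32 and 0.24. Macrophage markers in the chow genotype comparison reversed to 0.0602 without WT chow 2, in a range of −0.19 to 0.06 without single animals. Peroxisomal and microsomal fatty acid oxidation genes, compared by diet in KO males, went from a median of −0.24 to 0.01 without KO HFHS 3 while their test still pointed down (adjusted p = 0.996). No other named gene or list changed sign.

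With the replicate number as a block the counts were 2 for males on HFHS, 3 for males on chow, 7 for females, 17 averaged, 0 and 0 for the interactions, 2 and 24 for diet in WT and KO, 189 and 149 for sex in WT and KO, and 67 for lists. The diet calls changed more than these counts show. The block kept 1 of the 5 main calls in WT and 9 of the 28 in KO. In KO 20 genes were then higher and 4 lower, against 15 and 13 in the main fit. Animals with the same number showed no general pairing (correlation of deviations −0.122 to 0.211), and not every animal correlated best with its own number. In WT on HFHS, however, females 1, 2 and 3 each correlated best with the male of the same number (r = 0.0148, 0.0728 and 0.146).

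Among the other results, named genes kept their call in the 80 cases that the stricter filter still tested, and those it removed had no test there (the averaged count went from 23 to 19). They kept their call in 96 cases and lost it in 5 after quantile normalisation again, in 86 and 15 without a filter and in 692 and 215 without single animals. Lists kept theirs in 430 cases and lost it in 94 without single animals. Signal over background limited the reading of Nat1 and Nat3, which lay under the table median.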

Other observations

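Of the tests in this part, those of the iron genes and of the split of the HFHS males were chosen only after the result was seen.

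On the male-biased list of liver genes, 5 of the 6 males on HFHS lay between the females and all chow males, and KO 3 lay inside the chow range. These HFHS values are from Batch1 and the chow values from Batch2, where the second arrays of WT 1 and KO 3 were at 0.21 and 1.05. By group the means were −1.59, −2.02 and −1.77 in WT females and −1.69, −1.90 and −1.74 in KO females, 0.19, −0.32 and 0.31 in WT males on HFHS, −0.33, −0.27 and 0.98 in KO males on HFHS, 0.59 to 1.37 in WT males on chow and 1.04 to 1.63 in KO males on chow. Cyp2b13, Cyp4a12a and Cyp4a12b, which differ between the sexes in mouse liver, were among the genes called for diet in WT males.

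In males on HFHS, the split of the 6 animals with the most calls (17 genes) put WT 1, WT 3 and KO 3 against WT 2, KO 1 and KO 2. Their means on the male-biased list were 0.19, 0.31 and 0.98 against −0.32, −0.33 and −0.27.

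In males on HFHS, Hamp ran from 7.76 to 12.36 in KO and from 12.72 to 13.13 in WT (limma adjusted p = 0.227). The mitochondrial iron importer gene Slc25a37 was 0.67 higher in KO (exact permutation p = 0.1, limma adjusted p = 0.198). That permutation p is the smallest that 3 against 3 animals can give. The KO values of Slc25a37 (8.09 to 8.62) did not overlap those of WT (7.44 to 7.79). Alas2 differed by 0.22. Transferrin (Trf) was at 12.91 in KO and 12.83 in WT. No gene of this kind that was looked at passed the threshold. Most of them varied more in KO than in WT, such as Alas2 (SD 0.93 in KO and 0.19 in WT, n = 3 each) and Id1 (0.81 and 0.26). The exceptions were Trf (0.0158 and 0.0509) and Hbb-bt (1.33 and 1.39).

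The arrays of WT HFHS male 1 in the 2 batches correlated at r = 0.978 and those of KO HFHS male 3 at r = 0.977. The Batch1 array of the first animal correlated at 0.978 to 0.979 with other animals of its group and batch, and that of the second at 0.958 to 0.968. Unnamed probe sets were called in 1 case for males on chow and in 8 and 11 cases for the sex difference in WT and KO.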
